A study of Dugesia japonica with 16 samples.

How the data were processed

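RNA was measured in 16 sequencing libraries of the planarian flatworm *Dugesia japonica*, 4 libraries in each of 4 groups. Per the labels' protocols, worms were kept at 20 °C, starved for 7 days and decapitated behind the eyes. The posterior pieces were then held in water with MCTR3, PCTR3 or RCTR3 at 10 nM, or with vehicle (0.1% ethanol), and were collected 48 h later. RNA was extracted with TRIzol, enriched for polyadenylated RNA and sequenced in paired-end mode on an Illumina NextSeq instrument. The ethanol content of the compound groups, the number of worms per library and the day of each library preparation are not given in the sources used here.

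The deposited values are log2 TPM (length-corrected transcript abundance relative to the total of the library), one column per library, which the authors computed by assigning reads to *D. japonica* transcript sequences, per the labels and the series' design text. The submitters' processing notes name kallisto and sleuth, without versions or roles. The transcript sequence set, its version and any filter are not given in the sources used here. The file holds 44857 transcripts in 16873 assembly components, where a component is the part of the identifier shared by transcripts that the assembler kept together. A TPM of 0 appears in the file as 1 shared floor value of -34.92, and the next lowest value is -33.92. Turned back to the linear scale, the libraries sum to between 926.1 and 1129 kTPM (kilo-TPM), so the deposited values carry a further factor per library whose origin is not given in the sources used here. TPM keeps no read depth, so the depth of each library is unknown and no counting interval is given. The precision rests on the 4 libraries per group.

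The groups and replicate numbers came from the sample titles, and each column was matched to its title by its library name. The labels number the libraries 1 to 4 within each group and do not say whether they came from separate batches of worms. P-values therefore measure the spread between these libraries, which may be technical. None of the 120 pairs of libraries held identical values.

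Transcripts with a TPM of at least 1 in at least 4 of the 16 libraries were tested (28431 transcripts). Of these, 3060 were at 0 in 1 or more libraries, and 1.71% of the tested values were at 0. The test was limma 3.58.1 in R 4.3.3: a linear model with 4 group means fitted to the deposited log2 TPM of all 16 libraries, followed by empirical Bayes moderation with an intensity trend. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested transcripts, with a threshold of 0.05. The same model gave each compound against vehicle, each pair of compounds, the mean of the 3 compounds against vehicle, and an F test of any difference among the 4 groups. The floor makes log2 changes on the deposited scale reach 39.1 for transcripts at 0 in some libraries. Changes are therefore printed on the log2(TPM + 1) scale, with standard errors from the same model on that scale, which understates the change of low transcripts. Adjusted p-values are those of the deposited scale.

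The rule for named transcripts was fixed before the data were examined, as were the groups, the main tests and most of the other settings tried. Because the file pairs no identifier with a gene name, the rule allows 2 transcripts that rose and 2 that fell per comparison. They are those with the largest change among transcripts past the threshold whose 4 libraries of one group all lay on the same side of the 4 libraries of the other, or, where none qualified, those with the lowest p. Parts of the ranking by change were set after the data had been seen: it used the log2(TPM + 1) scale, and it kept to transcripts above 0 in every library of the groups compared, since the floor would otherwise have ranked transcripts by their number of zeros. Transcripts chosen by the lowest p were held to neither condition, so some of them were at 0 in libraries compared. The gene lists and the TRAF3 transcripts that were to be followed need gene names and were not analysed here.

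Library structure was described by principal components, Spearman correlations, the share of TPM in the most abundant transcripts and the number of transcripts at 1 TPM or more. Single measures were compared by exact two-sided permutation tests, whose smallest p for 4 libraries against 4 is 0.0286. A score along the main direction of difference was added after the data had been seen. It projects each library's log2(TPM + 1) values on the difference between the mean of the PCTR3 and RCTR3 groups and the mean of the vehicle and MCTR3 groups, scaled so that those means are 1 and 0. Because the comparisons against vehicle share the same 4 vehicle libraries, correlations and overlaps were set beside 20 simulations of unchanged groups, beside the overlap of independent lists, and beside values from vehicle libraries split 2 and 2.

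Transcript shares within components were also tested, after the data had been seen. Arcsine square roots of each transcript's share of its component's TPM were fitted with limma, and p-values were combined within each component by Simes' method. limma's diffSplice on log2(TPM + 1) was run first, and it was set aside for its false calls on simulated data after its counts on the deposited values had also been seen. In the simulation of PCTR3 against vehicle over 5801 components, with 200 changed 4-fold in 1 transcript, diffSplice recovered 146 with 35 false calls and the share test recovered 122 with 11. The transcript test was checked in the same way on 28431 simulated transcripts of PCTR3 against vehicle, of which 200 were changed. That is a far smaller share than the 22% called in the deposited values, and the adjustment is stricter where fewer transcripts change. The recovery on simulated data is therefore not the power of the reported comparison. The transcript test recovered 25.4% of simulated transcripts with a log2 change of 0.5, 50.7% with a log2 change of 1 and 74.2% with a log2 change of 2, with 6 false calls.

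The other settings fixed beforehand were pseudocounts of 0.1, 1 and 5, other filters on low values, other scalings between libraries (a common TPM sum, median centring, quantile normalization), other variance models, library weights, the replicate number as a block, only the compared groups in the fit, and leaving out each library. Settings added after the data had been seen were sums over components, a common total without the 100 most abundant transcripts, and the joint omission of vehicle replicate 4 and PCTR3 replicate 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.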

Results

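Transcript abundance was measured in the regenerating posterior pieces of *Dugesia japonica*, a freshwater planarian that regrows a lost head, 48 h after head resection. The 16 libraries fell into 4 groups of 4: vehicle, MCTR3, PCTR3 and RCTR3. The compounds are the cysteinyl conjugates of the maresin, protectin and resolvin families, named conjugates in tissue regeneration, and all are made from docosahexaenoic acid. They differ in the carbons that carry the cysteinyl and hydroxyl groups, and RCTR3 carries an additional hydroxyl group. Each was given at 10 nM for the same time, so responses could be compared at a matched dose. The labels number the vehicle and MCTR3 libraries 1 to 8 and the PCTR3 and RCTR3 libraries 9 to 16, so a comparison between these sides cannot tell treatment from position in the numbering. The values were log2 TPM, and the read depth of each library is unknown. Each library had between 24196 and 26124 transcripts at 1 TPM or more. The file pairs transcript identifiers with no gene names, so transcripts are named by identifier.

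The comparison of PCTR3 with vehicle asked which transcripts differed with the protectin conjugate during head regeneration. Between PCTR3 and vehicle, 6250 of 28431 tested transcripts differed, of which 3058 rose and 3192 fell (limma, adjusted p under the threshold of 0.05). These groups also differ in library numbering, so the compound is not shown to be the cause. Most changes were small: the median log2(TPM + 1) change was 0.571 among transcripts that rose and -0.402 among those that fell, and 382 rises and 144 falls exceeded 2-fold on that scale. The transcript comp143021_c0_seq11 rose from 2.15 ± 1.06 TPM in vehicle to 125 ± 97.1 TPM with PCTR3 (SD, n = 4), a log2(TPM + 1) change of 5.04 (SE 0.59; limma adjusted p = 0.00045). comp143819_c0_seq5 rose from 25.2 ± 10.2 to 329 ± 196 TPM (limma adjusted p = 0.0015). comp142099_c0_seq9 fell from 139 ± 34.9 to 20 ± 12.8 TPM (log2(TPM + 1) change -2.90, SE 0.32; limma adjusted p = 0.00039). comp121080_c0_seq2 fell from 60.6 ± 21.6 TPM in vehicle to at most 0.0428 TPM in any PCTR3 library (limma adjusted p = 0.012), a call that ended under a filter of 5 TPM (adjusted p = 0.22, in a range of 4.6e-12 to 0.22 over all alternatives). The balance of rises and falls depended on the scaling between libraries, with 4966 rises and 1737 falls after rescaling to a common TPM sum, 2236 and 4364 after median centring, and 4335 and 2079 with a total that left out the 100 most abundant transcripts. Without PCTR3 replicate 2 the number of changed transcripts was 4149.

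The comparison of RCTR3 with vehicle asked the same of the resolvin conjugate. Of the 28431 transcripts, 7509 differed between RCTR3 and vehicle, with 3659 rises and 3850 falls (limma, adjusted p under 0.05). Here too the compound cannot be told apart from the library numbering. The median log2(TPM + 1) change was 0.585 among rises and -0.431 among falls, and 518 rises and 230 falls exceeded 2-fold. comp143021_c0_seq11 again rose, from 2.15 ± 1.06 to 127 ± 71.1 TPM (SD, n = 4; log2(TPM + 1) change 5.28, SE 0.59; limma adjusted p = 0.00021). comp133973_c0_seq1 rose from 1.18 ± 0.637 to 26.5 ± 8.4 TPM (limma adjusted p = 0.013), a call that ended under quantile normalization (adjusted p = 0.16, the highest of its alternatives, which began at 7.7e-05). comp146001_c0_seq8 fell from 38 ± 6.62 to 3.79 ± 2.41 TPM (log2(TPM + 1) change -3.17, SE 0.36; limma adjusted p = 0.00025). comp145183_c0_seq22 fell from 21.2 ± 2.05 TPM in vehicle to at most 1.65e-05 TPM in any RCTR3 library (limma adjusted p = 0.0027). Rescaling to a common TPM sum gave 6163 rises and 2008 falls, median centring 2615 and 5330, and the total without the 100 most abundant transcripts 5370 and 2445.

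**Figure D1:**
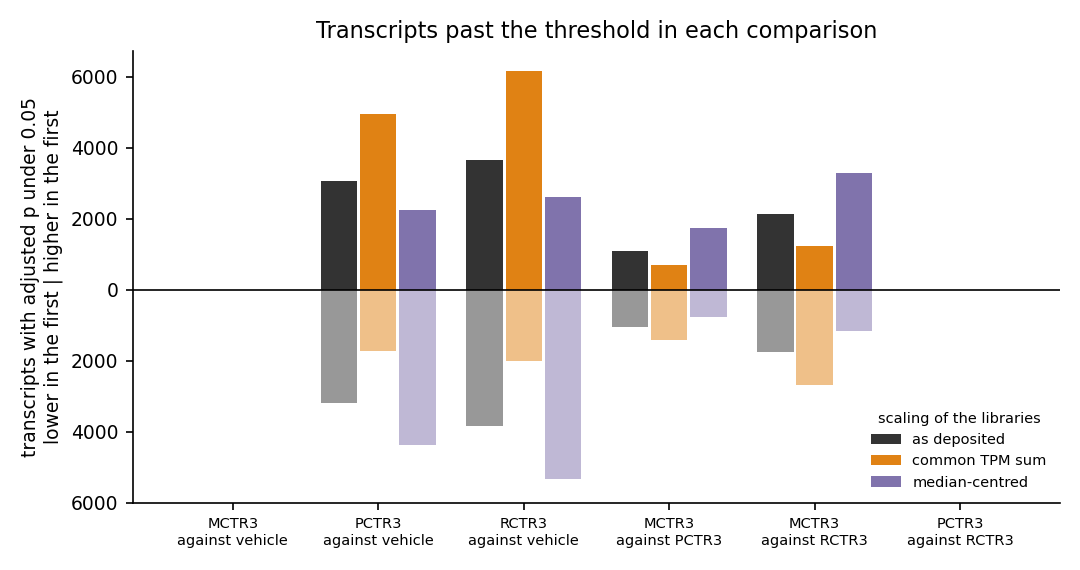
Transcripts past the threshold in each comparison (limma, adjusted p under 0.05, of 28431 tested), drawn upward where higher and downward where lower in the group named first, under 3 scalings of the libraries. PCTR3 and RCTR3 have tall bars against vehicle under each scaling (6250 and 7509 transcripts with the deposited one), while the split for PCTR3 moves from 3058 rises and 3192 falls to 4966 and 1737 after rescaling to a common TPM sum.

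PCTR3 and RCTR3 changed largely overlapping sets of transcripts, and no transcript differed between them. Of the transcripts that rose, 2658 were called for both compounds, and of those that fell, 2789; 0 were called in opposite directions. Independent lists of these sizes would share 394 rises and 432 falls. Simulated unchanged groups against the same vehicle libraries shared 0 calls, which is no measure of the overlap, since few calls are made where nothing differs. When each compound was set against a different pair of vehicle libraries, between 1957 and 2696 transcripts were still called in the same direction, against 262 to 386 for independent lists. Across transcripts, which are not independent replicates, the log2(TPM + 1) changes of the compounds had r = 0.866, against 0.498 in simulated unchanged groups and 0.652 with separate vehicle pairs. The covariance was 0.196 against a simulated 0.0316, a difference of 0.164.

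Set against each other directly, PCTR3 and RCTR3 differed in 0 transcripts by limma (smallest adjusted p = 1), with 972 transcripts (3.42%) at an unadjusted p under 0.05. The 95% confidence interval of the difference lay within 2-fold on the log2(TPM + 1) scale for 86.5% of all tested transcripts, and for 98.5% of the 10716 with a mean of at least 10 TPM (92.7% within 1.5-fold). Smaller differences, and differences in rare transcripts, are not excluded. The transcripts with the lowest p included comp139376_c2_seq10, with 0.237 ± 0.288 TPM for PCTR3 and 3.01 ± 0.668 TPM for RCTR3 (SD, n = 4; limma adjusted p = 1), and comp132567_c0_seq3, with 3.42 ± 0.785 and 5.72 ± 0.439 TPM (limma adjusted p = 1). On the other side, comp129091_c0_seq1 and comp134769_c0_seq3 were above 0 in all PCTR3 libraries and listed at 0 in RCTR3 replicates 2, 3 and 4 (limma adjusted p = 1 for each). Both passed the threshold without RCTR3 replicate 1, and comp139376_c2_seq10 passed it without PCTR3 replicate 3. Leaving out 1 library gave few calls: 8 without PCTR3 replicate 3, 1 without PCTR3 replicate 4, 3 without RCTR3 replicate 1, 2 without RCTR3 replicate 2 and 3 without RCTR3 replicate 4.

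**Figure D2:**
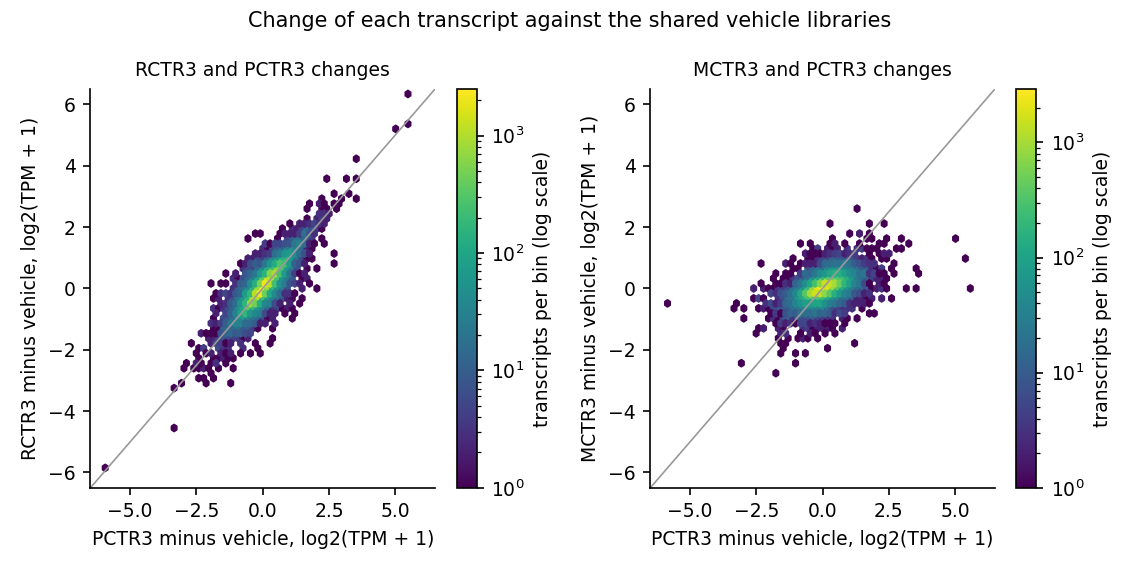
Change of each of the 28431 tested transcripts on the log2(TPM + 1) scale, with PCTR3 minus vehicle on the horizontal axis and RCTR3 (left) or MCTR3 (right) minus vehicle on the vertical axis; colour gives the number of transcripts per bin on a log scale, and the line marks equal change. The RCTR3 changes lie along the line (r = 0.866, against 0.498 for unchanged groups that share the vehicle libraries). The MCTR3 changes are smaller (r = 0.544, against 0.499, and 0.234 with separate vehicle pairs), with a covariance of 0.0661 against a simulated 0.0315. The simulated r is that of groups which are all unchanged, so its closeness to 0.544 does not measure the part of the shared vehicle libraries.

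Between MCTR3, the maresin conjugate, and vehicle, 1 transcript differed (limma, adjusted p under 0.05), while 2046 transcripts (7.2%) had an unadjusted p under 0.05. The transcript, comp127030_c0_seq2, was listed at 0 in all 4 vehicle libraries and lay between 0.39 and 1.69 TPM in the MCTR3 libraries (limma adjusted p = 0.0061). The call ended with each pseudocount tried, with the replicate number as a block, and without MCTR3 replicate 1 or 4 or PCTR3 replicate 2. With a pseudocount of 1 its limma adjusted p was 0.66, in a range of 3e-13 to 0.67 over all alternatives. The next lowest p belonged to comp132411_c1_seq1, with 2.9 ± 0.434 TPM in vehicle and 6.57 ± 1.38 TPM with MCTR3 (SD, n = 4; limma adjusted p = 0.51). comp135446_c0_seq1 had 3.41 ± 0.694 and 1.63 ± 0.0874 TPM (limma adjusted p = 0.51), and comp143035_c0_seq56 had 17 ± 2.22 and 10.9 ± 1.42 TPM (limma adjusted p = 0.65). The 95% interval of the MCTR3 change on the log2(TPM + 1) scale lay within 2-fold for 86% of all tested transcripts. Of the 10716 with a mean of at least 10 TPM it lay within 2-fold for 98% and within 1.5-fold for 90.5%, against 93.1% and 70.2% for PCTR3 and 91.8% and 66.8% for RCTR3. The number of calls was 3, 7 and 2 without vehicle replicates 1, 2 and 4, 0, 2, 2 and 0 without MCTR3 replicates 1 to 4, and 0 without PCTR3 replicate 2.

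MCTR3 differed from both other compounds at the same dose and time. Against PCTR3, 2146 transcripts differed, 1098 higher and 1048 lower with MCTR3, and against RCTR3, 3862 differed, 2124 higher and 1738 lower (limma, adjusted p under 0.05). comp143021_c0_seq11 stood at 10.5 ± 6.9 TPM with MCTR3 and was lower than with PCTR3 (log2(TPM + 1) difference -3.41, SE 0.59; limma adjusted p = 0.014) and than with RCTR3 (difference -3.64, SE 0.59; limma adjusted p = 0.0046). comp142099_c0_seq9 stood at 85.8 ± 10.4 TPM with MCTR3, higher than the 20 ± 12.8 TPM with PCTR3 (SD, n = 4; limma adjusted p = 0.0077). comp146001_c0_seq8 stood at 27.9 ± 4.53 TPM with MCTR3, higher than the 3.79 ± 2.41 TPM with RCTR3 (limma adjusted p = 0.0028), and comp145183_c0_seq22 at 14.2 ± 1.95 TPM (limma adjusted p = 0.0084). comp134262_c1_seq1 stood at 0.279 ± 0.13 TPM with MCTR3 and 7.84 ± 1.9 TPM with RCTR3 (limma adjusted p = 0.029), a call that ended under quantile normalization and without MCTR3 replicate 2, 3 or 4 or any 1 RCTR3 library. comp143819_c0_seq5 was lower with MCTR3 than with PCTR3 (39.6 ± 17.4 against 329 ± 196 TPM; limma adjusted p = 0.017), and that call ended without PCTR3 replicate 1 or 2. comp121080_c0_seq2 was higher with MCTR3 than with PCTR3 (39.5 ± 7.03 TPM against at most 0.0428 TPM; limma adjusted p = 0.034), a call that ended under a filter of 5 TPM and without vehicle replicate 1, any 1 MCTR3 library or PCTR3 replicate 1, 2 or 4. The count against PCTR3 was 1415, 818, 731 and 772 without MCTR3 replicates 1 to 4, 482, 334 and 3333 without PCTR3 replicates 1, 2 and 3, and the count against RCTR3 was 2446 without MCTR3 replicate 3 and 2122 without RCTR3 replicate 1. Rescaling to a common TPM sum turned the splits to 708 higher and 1414 lower against PCTR3 and 1243 and 2671 against RCTR3. Median centring gave 1740 and 755, and 3291 and 1161, and the total without the 100 most abundant transcripts gave 847 and 1311, and 1477 and 2334.

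**Figure D3:**
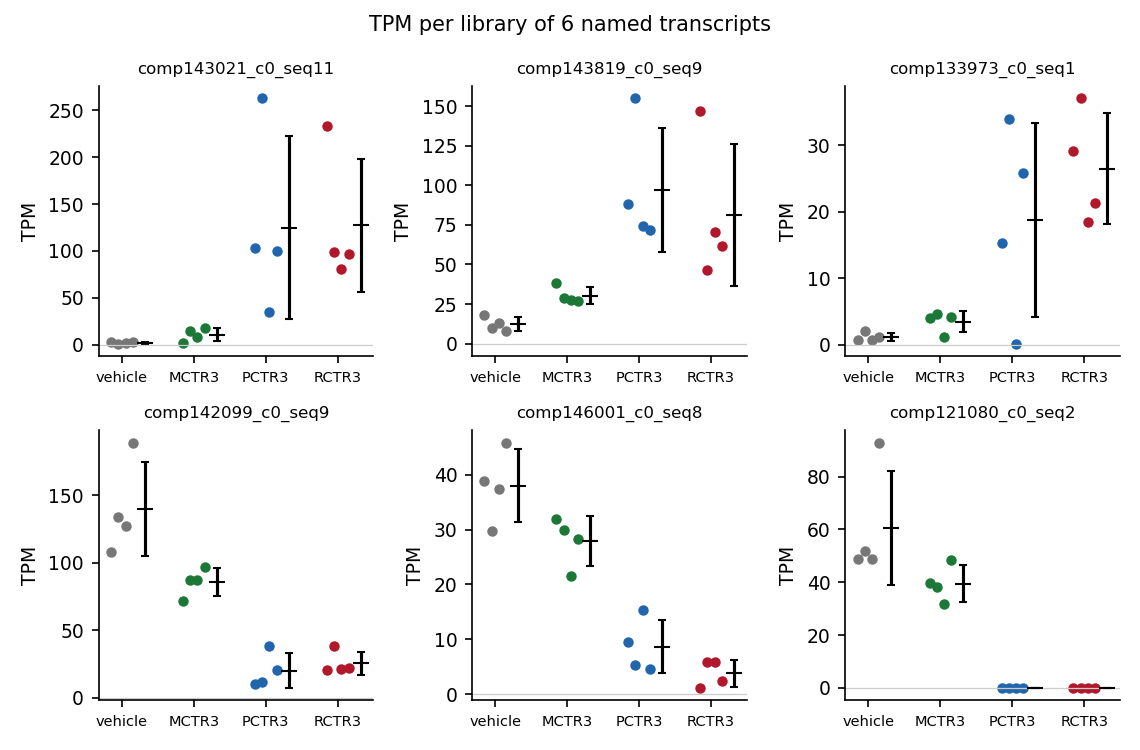
TPM in each of the 16 libraries (points) for 6 named transcripts, with group means and SD (bars, n = 4). The MCTR3 means lie between those of vehicle and RCTR3 in each panel, as for comp143021_c0_seq11 with 2.15 TPM in vehicle, 10.5 with MCTR3, 125 with PCTR3 and 127 with RCTR3. The 6 were picked from transcripts named for a large change between groups, which favours a middle position of MCTR3. Not every named transcript has that position, comp134262_c1_seq1 being an exception that is not drawn.

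The mean of the 3 compounds differed from vehicle in 6087 transcripts, with 3011 rises and 3076 falls (limma, adjusted p under 0.05). The F test of any difference among the 4 groups called 6196. A difference in the mean can come from PCTR3 and RCTR3 alone, and MCTR3 against vehicle had 1 call, so these are not shown to be responses to all 3. comp143819_c0_seq9 had 12.4 ± 4.29 TPM in vehicle, 30.3 ± 5.2 with MCTR3, 97.3 ± 39.3 with PCTR3 and 81.4 ± 45.1 with RCTR3 (SD, n = 4; log2(TPM + 1) change of the mean 2.22, SE 0.26; limma adjusted p = 0.00067). comp145383_c1_seq5 rose from 2.61 ± 0.645 TPM to 19.2 ± 11.3 with PCTR3 and 15.6 ± 7.66 with RCTR3, with 4.19 ± 1.02 TPM for MCTR3 (limma adjusted p = 0.002 for the mean). comp142099_c0_seq9 fell from 139 ± 34.9 TPM to 20 ± 12.8 with PCTR3 and 25.4 ± 8.68 with RCTR3, with 85.8 ± 10.4 TPM for MCTR3 (limma adjusted p = 0.00077 for the mean). For MCTR3 alone against vehicle, none of these transcripts passed the threshold. The limma adjusted p was 0.65 for comp143819_c0_seq9, 0.7 for comp145383_c1_seq5 and 0.68 for comp142099_c0_seq9. comp145183_c0_seq22 also fell (limma adjusted p = 0.036), a call that ended without any 1 vehicle or MCTR3 library or PCTR3 replicate 2. The count without vehicle replicate 4 was 3395. Rescaling to a common TPM sum gave 5191 rises and 1453 falls, median centring 2218 and 4242, and the total without the 100 most abundant transcripts 4517 and 1837.

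The libraries separated into vehicle and MCTR3 on the one side and PCTR3 and RCTR3 on the other. The leading principal component held 30.4% of the variance, and the next 7.07%. Its scores ran from -60.55 to -32.95 in vehicle, from -28.66 to -20.9 with MCTR3, from 6.523 to 57.05 with PCTR3 and from 24.55 to 54.05 with RCTR3. On the axis score the means were -0.101 ± 0.146 in vehicle, 0.101 ± 0.0419 with MCTR3, 0.962 ± 0.257 with PCTR3 and 1.04 ± 0.148 with RCTR3 (SD, n = 4). The 4 MCTR3 libraries all scored above the 4 vehicle libraries (exact two-sided permutation p = 0.0286, the smallest the design allows; Benjamini-Hochberg 0.0571 over 2 tests), with an exact p of 0.0571 without any 1 MCTR3 library. RCTR3 and PCTR3 differed by 0.0767 (exact permutation p = 0.714). Spearman correlations between libraries lay between 0.885 and 0.959, with a median of 0.929 across the 2 sides. The 2 sides are also the libraries numbered 1 to 8 and 9 to 16 in the labels, which give no batch.

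**Figure D4:**
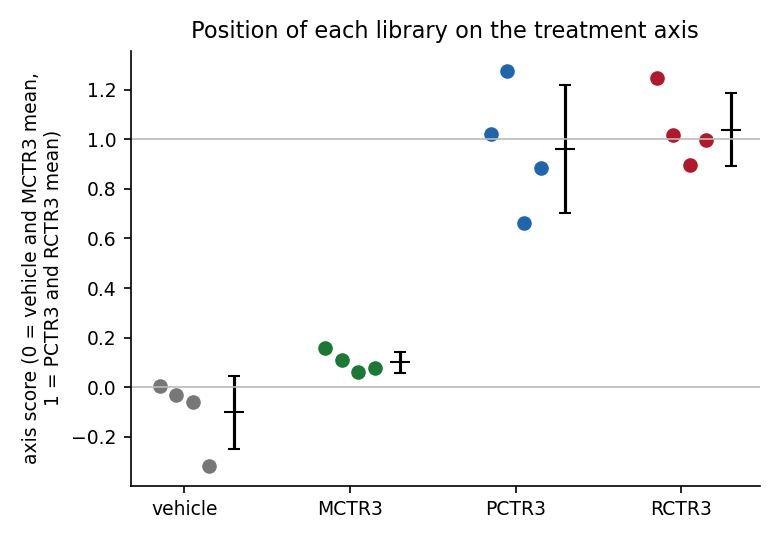
Axis score of each library (points) by group, with the group mean and SD (bars, n = 4); 0 is the mean of the vehicle and MCTR3 groups and 1 the mean of the PCTR3 and RCTR3 groups. The 4 MCTR3 libraries lie between 0.06107 and 0.1569, above the 4 vehicle libraries, and the lowest PCTR3 library lies at 0.6623.

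Among called transcripts the share of rises was lower in abundant than in rarer transcripts, and with the deposited scaling abundant ones mostly fell. In the least abundant quintile of the tested transcripts (median 1.03 TPM), 77.7% of the transcripts called for PCTR3 had risen, against 30.5% in the most abundant quintile (median 51.3 TPM). For RCTR3 the shares were 81.1% and 29.7%. In the most abundant quintile the balance moved with the scaling. The scalings counted by quintile, beside the deposited one, were those that raised the share of rises over all PCTR3 calls. Median centring (2236 rises and 4364 falls over all PCTR3 calls) and quantile normalization (2784 and 2991) were not counted by quintile. With the total without the 100 most abundant transcripts the share of rises was 50.8% for PCTR3 and 51.2% for RCTR3. After rescaling to a common TPM sum, 1481 rose and 1003 fell with PCTR3 and 1652 rose and 1113 fell with RCTR3. These rescaled counts came from a fit on log2(TPM + 1), so they differ from the deposited counts in the fitted scale as well as in the scaling. Of the 100 most abundant transcripts, 2 rose and 39 fell with PCTR3, and 2 rose and 47 fell with RCTR3. After rescaling to a common TPM sum, also in the fit on log2(TPM + 1), 11 rose and 34 fell with PCTR3, and 13 rose and 36 fell with RCTR3. The 100 most abundant transcripts of each library held 29.5% ± 0.725 of all TPM in vehicle, 28.6% ± 0.125 with MCTR3, 27.7% ± 0.483 with PCTR3 and 27.4% ± 0.416 with RCTR3 (SD, n = 4). Against vehicle this gave an exact permutation p of 0.0286 for PCTR3 and for RCTR3 and 0.0857 for MCTR3 (Benjamini-Hochberg 0.0735, 0.0735 and 0.14 over 18 tests), so none passed after adjustment. The unadjusted p for PCTR3 was 0.0571 without vehicle replicate 4 or any 1 PCTR3 library, that for RCTR3 was 0.0571 without RCTR3 replicate 1 or 2, and that for MCTR3 was 0.0286 without vehicle replicate 3 (exact permutation tests). The TPM sums of the libraries, which carry the further factor per library, were 1070 ± 43.8 kTPM (kilo-TPM) in vehicle, 1010 ± 9.78 with MCTR3, 974 ± 15.8 with PCTR3 and 953 ± 18 with RCTR3 (SD, n = 4). All 4 libraries of each compound lay below all 4 vehicle libraries, with differences of -52.4, -91.3 and -113 kTPM (exact permutation p = 0.0286 for each, Benjamini-Hochberg 0.0735 over 18 tests). The MCTR3 difference was -31.2 kTPM without vehicle replicate 4, and the exact p was 0.0571 for MCTR3 without any 1 MCTR3 library and for PCTR3 without PCTR3 replicate 1. Transcripts at 1 TPM or more numbered 24892 ± 472 in vehicle, 25735 ± 231 with PCTR3 and 25956 ± 174 with RCTR3 (exact permutation p = 0.0286 for each, Benjamini-Hochberg 0.0735; 0.0571 for PCTR3 without PCTR3 replicate 2), and 25204 ± 148 with MCTR3 (exact permutation p = 0.229, Benjamini-Hochberg 0.317).

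**Figure D5:**
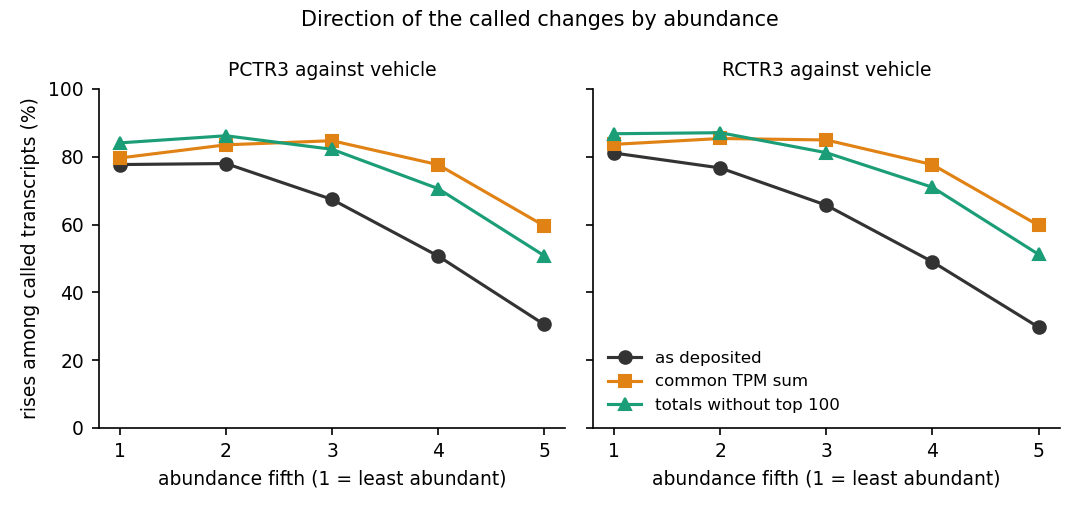
Percentage of rises among the transcripts called in each abundance quintile (1 = least abundant) for PCTR3 and RCTR3 against vehicle, under 3 scalings of the libraries. The values under the common TPM sum were fitted on log2(TPM + 1), and the others on the deposited log2 scale. With the deposited values the share falls from 77.7% to 30.5% for PCTR3, and with a total that leaves out the 100 most abundant transcripts from 84.1% to 50.8%. Falls thus outnumber rises in the most abundant quintile only with the deposited scaling among these 3. Median centring and quantile normalization, under which falls outnumbered rises over all PCTR3 calls, were not counted by quintile.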

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

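The tests of library numbering, scaling and depth described here were chosen only after the results they bear on were seen; those of vehicle replicate 4, of separate vehicle libraries and of the 100 most abundant transcripts were set down before their results were seen.

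The compound groups differed from each other in 2146 transcripts between MCTR3 and PCTR3 and in 3862 between MCTR3 and RCTR3 (limma, adjusted p under 0.05), and both comparisons also part libraries 1 to 8 from 9 to 16. Of 35 splits of the 8 libraries, only the real one gave as many in each case (1 of 35), with 2 as the highest other count in both. A share of 1 of 35 is the smallest that 35 splits can give, and a split that mixes differing groups also widens the spread. The splits thus argue against chance without excluding it. The same holds for the 6250 transcripts of PCTR3 against vehicle (1 of 35 splits, highest other 1) and the 7509 of RCTR3 (1 of 35, highest other 2). It also holds for the 6087 of the mean of the compounds (1 of 100, highest other 3) and the 6196 among the 4 groups (1 of 100, highest other 4). For MCTR3 against vehicle, 23 of 35 splits gave 1 or more transcripts, up to 3, so the splits give nothing against chance there. For the 0 of PCTR3 against RCTR3 the splits are no test, since each of the 35 gives 0 or more (highest other 5).

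PCTR3 and RCTR3 libraries differed from vehicle in 6250 and 7509 transcripts and from each other in 0 (limma, adjusted p under 0.05; 972 at an unadjusted p under 0.05). The authors' scaling as the cause of the number of calls is argued against by counts under other scalings of at least 92.4% of the reported PCTR3 count. The 3058 rises and 3192 falls became 4966 and 1737 with a common TPM sum and 2236 and 4364 with median centring. Scaling therefore stays open for which transcripts were called and in which direction. A depth difference acting on rare transcripts leaves unexplained the 44.2% of the most abundant quintile called for PCTR3, while it stays open for the 4.1% called in the least abundant quintile. A steady drift along the library numbering would need the axis score to rise within groups by the 0.107 per library seen between group means, and the mean slope within groups was -0.0793 (SE 0.0173). The axis score fell with the number within each group, with slopes of -0.0989 in vehicle, -0.0282 with MCTR3, -0.103 with PCTR3 and -0.0874 with RCTR3. The cause of this fall was not tested. Separate handling of libraries 1 to 8 and 9 to 16 stays open: only 1 transcript differed between groups on the same side of that division, and treatment and numbering cannot be told apart because each group holds consecutive numbers. A response common to PCTR3 and RCTR3 is the biological explanation the design offers, and it stays open beside it.

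MCTR3 libraries sat between vehicle and the other compounds. Without vehicle replicate 4 the distance from vehicle kept 78.3% of its size and the groups stayed apart. With separate vehicle libraries MCTR3 carried on average 0.225 of the PCTR3 and RCTR3 change, and at least 0.153 in each of 6 splits of the vehicle libraries, which argues against the shared controls as the cause. A division of handling at libraries 8 and 9 would leave MCTR3 level with vehicle, and the exact permutation p against that was 0.0286 (0.0571 after adjustment over 2 tests, and 0.0571 unadjusted without any 1 MCTR3 library), which does not decide it. A weaker response in the same direction, that division and handling that differed from group to group all stay open, and treatment and numbering cannot be told apart because each group holds consecutive numbers.

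Among called transcripts, with the deposited scaling, the abundant ones mostly fell and the rarer ones mostly rose. After rescaling to a common TPM sum, in a fit on log2(TPM + 1), the abundant ones mostly rose too (1481 rises and 1003 falls with PCTR3). With the total without the 100 most abundant transcripts, on the deposited log2 scale, 50.8% of the most abundant quintile's PCTR3 calls were rises. Both of these scalings raise the share of rises, and median centring and quantile normalization were not counted by quintile. The direction moves with the scaling, so the difference between quintiles is the pattern weighed. Totals without the 100 most abundant transcripts left the share of rises 33.3 (PCTR3) and 35.6 (RCTR3) percentage points higher in the least than in the most abundant quintile. That gap had been set beforehand as evidence against these transcripts as the cause, wrongly, since a new total is 1 factor per library and moves all transcripts of a library alike on the log2 scale. The part of the 100 most abundant transcripts, a shift in RNA composition in the worms and one made during library preparation all stay open, and no biological explanation beyond the treatment groups was tested.

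Single libraries stood far from the other 3 of their group in 16 of 99 groups of 4 values examined. Chance gives about 1 in 20, or 5, for independent and normally distributed values. Many groups held TPM of selected transcripts, some at or near 0, and the library measures depend on each other. The 16 are therefore not shown to be an excess. Among library measures, RCTR3 replicate 2 summed to 926.1 kTPM (kilo-TPM) against 959.3 to 965.7 in the others. MCTR3 replicate 1 had 25426 transcripts at 1 TPM or more (others 25121 to 25135), and PCTR3 replicate 3 had 38625 transcripts above 0 (others 37651 to 37755). Vehicle replicate 3 held 8.125% of TPM in its 10 most abundant transcripts (others 8.857% to 8.997%). The median Spearman correlation with the own group was 0.9521 in MCTR3 replicate 2 (others 0.9502 to 0.9505) and 0.9467 in PCTR3 replicate 2 (others 0.9514 to 0.9519).

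Among named transcripts, comp121080_c0_seq2 stood apart in vehicle replicate 4 at 92.9 TPM (others 48.7 to 51.8), in PCTR3 replicate 3 at 0.0428 TPM and in RCTR3 replicate 4 at 0.0266 TPM, with the others at 1.76e-09 to 6.19e-09 TPM in PCTR3 and at 0 to 8.23e-10 TPM in RCTR3. comp143021_c0_seq11 was at 233 TPM in RCTR3 replicate 1 (others 81.3 to 98.5), and comp142099_c0_seq9 at 38.4 TPM in RCTR3 replicate 2 (others 20.5 to 21.8). comp133973_c0_seq1 was at 1.18 TPM in MCTR3 replicate 3 (others 4.11 to 4.65), comp127030_c0_seq2 at 1.69 TPM in MCTR3 replicate 4 (others 0.39 to 0.504) and comp135446_c0_seq1 at 2.91 TPM in PCTR3 replicate 1 (others 3.99 to 4.11). RCTR3 replicate 1 had 1.22 TPM of comp129091_c0_seq1 and 1.86 TPM of comp134769_c0_seq3, both listed at 0 in the other 3 RCTR3 libraries.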

How the results depend on the processing

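The component sums, the total without the 100 most abundant transcripts, the joint omission of vehicle replicate 4 and PCTR3 replicate 3, and every alternative for the axis score, the library shares and the transcript shares were chosen after the data had been seen; the cause of each change below was not tested unless the alternative itself lowers the number of libraries or transcripts. Apart from the omission of libraries, the counts of PCTR3 against vehicle (4349 to 6874), RCTR3 against vehicle (5892 to 8274), MCTR3 against RCTR3 (3061 to 5362) and the F test (5533 to 6971) stayed within 1.5 times the reported count under all alternatives. For MCTR3 against vehicle the count was 0 with pseudocounts of 1 and 5, with filters of 5 TPM or of 1 TPM in all 16 libraries, with component sums and with only the compared groups, and 2 with no filter or without vehicle replicate 4 and PCTR3 replicate 3 together. For MCTR3 against PCTR3 it was 1414 with no filter, 3325 with library weights, 1207 with only the compared groups and 3941 without those 2 libraries. PCTR3 against RCTR3 gave 3 with no filter and 6 without those 2 libraries, and the mean of the compounds gave 4057 without them. The overlap of PCTR3 and RCTR3 calls was 2050, 1958, 2623, 1957, 2558 and 2696 over the 6 vehicle splits, where each compound had 2 vehicle libraries in place of 4. Leaving out 1 library gave ranges of 0 to 7 for MCTR3, 4149 to 6513 for PCTR3 and 5806 to 7723 for RCTR3 against vehicle; 334 to 3333 for MCTR3 against PCTR3, 2122 to 4487 for MCTR3 against RCTR3 and 0 to 8 for PCTR3 against RCTR3. The ranges were 3395 to 6421 for the mean of the compounds, 5166 to 6408 for the F test and 3832 to 5532 for the overlap. The MCTR3 distance on the axis (0.203) was 0.167 to 0.253 under 6 other scales and scalings, and 0.153 to 0.261 without 1 library, where the exact permutation p reached 0.0571 without any 1 MCTR3 library. The share of the 100 most abundant transcripts differed from vehicle by -1.23 to -0.648 points for MCTR3, -2.11 to -1.52 for PCTR3 and -2.47 to -1.89 for RCTR3 without 1 library. The TPM sums differed by -64.6 to -31.2, -103 to -70.2 and -125 to -91.4 kTPM, and the transcripts at 1 TPM or more by 80.6 to 425, 611 to 955 and 832 to 1180, for MCTR3, PCTR3 and RCTR3 in turn. Rescaling to a common TPM sum moved the median log2 change of all transcripts from 0.034 to 0.162 for PCTR3 and from 0.036 to 0.196 for RCTR3; it was 0.127 and 0.153 with the total without the 100 most abundant transcripts, -0.056 and -0.071 with median centring, and -0.019 and -0.02 with quantile normalization. Of 854 alternative values of 28 named results, 812 kept direction and side of the threshold, 38 lost the call, 4 gained one and 0 changed direction. The 812 include alternatives of named results that had not passed the threshold and stayed uncalled, as for PCTR3 against RCTR3. The share kept among results that had passed is therefore lower. Depth is unknown, so no limit from depth can be given; rare transcripts have the least power.

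The replicate number as a block gave 1, 6002 and 7194 transcripts for MCTR3, PCTR3 and RCTR3 against vehicle, 2210, 3777 and 0 between MCTR3 and PCTR3, MCTR3 and RCTR3, and PCTR3 and RCTR3, 5782 for the mean of the compounds, 5732 for the F test and 5246 shared. The block ended the call of comp127030_c0_seq2. Residuals of libraries with the same number correlated by -0.067 to 0.11 over 24 pairs, 2 of them over 0.1. Of the 16 libraries, 5 correlated best with one of their own number, so the numbers were not taken as pairs. In each group, however, replicates 1 and 2 scored higher on the axis than replicates 3 and 4. A match by own number does not test a difference shared by several numbers, so structure along the numbers stays open. Gene list tests and sums over gene names were not run, because the file pairs identifiers with no gene names.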

Other observations

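The tests of transcript shares and component sums, and the counts of transcripts at 0, were chosen after the data had been seen. The relative use of transcripts within assembly components also differed between vehicle and the PCTR3 and RCTR3 groups, comparisons in which treatment and the numbering of the libraries cannot be told apart. Of 5801 components with 2 or more tested transcripts, 751 differed in their transcript shares between PCTR3 and vehicle and 1081 between RCTR3 and vehicle (limma on shares, adjusted p under 0.05), and in 390 and 526 of these the component's summed TPM did not pass the threshold, which does not show that it was unchanged. MCTR3 and vehicle differed in 0 (341 at an unadjusted p under 0.05; 27 by diffSplice), and PCTR3 and RCTR3 differed in 0 (247 at an unadjusted p under 0.05; 23 by diffSplice). In comp121080_c0, a component singled out after its values were seen, comp121080_c0_seq2 made up 57.2% ± 14.4 of the TPM of it and comp121080_c0_seq1 in vehicle and 42.3% ± 7.63 with MCTR3 (SD, n = 4), and at most 0.0485% in any PCTR3 or RCTR3 library. Over the same groups comp121080_c0_seq1 stood at 43.6 ± 12.7, 53.8 ± 7.24, 83.4 ± 4.14 and 78.1 ± 3.29 TPM. The summed TPM of both was 104 ± 9.63 in vehicle, 93.3 ± 2.06 with MCTR3, 83.4 ± 4.15 with PCTR3 and 78.1 ± 3.3 with RCTR3. Without the sequences, splicing, alleles and the assignment of shared reads to near-identical transcripts cannot be separated here.

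Splits of the libraries argue against chance, without excluding it, for the share changes of PCTR3 (751, with 1 of 35 splits as large and 2 as the highest other). They do so too for those of RCTR3 (1081, with 1 of 35 and 2 as the highest other). For the 0 of MCTR3 against vehicle (highest other 1) and the 0 of PCTR3 against RCTR3 (highest other 2) the splits are no test, since each of the 35 gives 0 or more. By diffSplice the counts were 1467 for PCTR3 and 1712 for RCTR3. For PCTR3 the count was 472, 488, 459 and 268 without vehicle replicates 1 to 4, and 303 and 284 without PCTR3 replicates 1 and 2. For RCTR3 it was 513 without vehicle replicate 4 and 659 without RCTR3 replicate 1. MCTR3 gave 1 without vehicle replicate 1, and PCTR3 against RCTR3 gave 1 without vehicle replicate 4 or RCTR3 replicate 4.

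Summed over components, 3019 of 15762 rose and 3165 fell with PCTR3, and 3418 rose and 3630 fell with RCTR3 (limma, adjusted p under 0.05). MCTR3 changed 0 components (1509 at an unadjusted p under 0.05), and PCTR3 and RCTR3 differed in 0 (477). Of the 621 components with 2 or more transcripts called for PCTR3, 286 held both a rise and a fall. For RCTR3 it was 395 of 821. In 100 shuffles of the calls over all tested transcripts, the median number holding both was 482 for PCTR3 and 640.5 for RCTR3. Those shuffles did not keep the number of components with 2 or more calls, so they do not test whether directions agree within components.

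Some transcripts were above 0 in all libraries of a group and listed at 0 in all of another. Any value over the floor counted as above 0, and tested transcripts held values as low as 8.23e-10 TPM. These counts therefore do not show presence against absence. PCTR3 and vehicle parted 25 transcripts in this way, 13 above 0 with PCTR3 and 12 above 0 in vehicle, against at most 12 in other splits of the same 8 libraries. RCTR3 and vehicle parted 19, against at most 7. The number was 3 for MCTR3 and vehicle, with up to 7 in other splits, and 1 for PCTR3 and RCTR3, with up to 8.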
